A study of Mus musculus with 6 samples.

How the data were processed

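The deposited table held whole-number read counts for 52459 rows named by gene symbol in 6 libraries, 3 of MYC_On and 3 of MYC_Off liver tumour tissue. Total RNA was extracted from flash frozen tumours with a column kit and libraries were made by the sequencing provider's protocol, per the labels' protocols. Per the submitters' processing notes, the authors used Trimmomatic, STAR, Picard, featureCounts and DESeq2 with the mm10 build. Versions, gene annotation, strand setting and the handling of reads with several matches are not given in the sources used here. The deposited counts are not normalized: column totals ran from 16292718 to 19265623 reads. Gapdh and several mitochondrial genes had very few reads for genes of their abundance, so reads shared with copies elsewhere appear not to have been counted, and members of multigene families are uncertain. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. In 26 rows the symbol had been turned into a date, and 2 rows repeated a symbol, so these were kept under a row number. Of the symbols, 91.7% matched GENCODE mouse release 21, which is on mm10 and gave the coordinates.

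Groups and replicate numbers came from the sample titles. MYC_Off was compared with MYC_On with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM scaling, a robust quasi-likelihood fit and test, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors were derived from the fold change and the F statistic. CPM values are TMM-scaled, and log2 CPM for list medians used a prior count of 2. For genes with 1 to 3 reads over a group the ratio of reads is given with its exact 95% interval. Setting such members of lists to a floor of 3 reads per group affected 5 members of 3 lists and moved a list median by at most 0.02. No 2 libraries of a group held identical values or agreed within sampling noise: chi-square per degree of freedom was at least 35.7.

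The tests, the 34 gene lists (23 on the question and 11 for other cell types, tissue handling and library type) and the alternatives were set before the data were examined, except where stated. The 32 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. Genes named in the text are Myc, the 6 largest increases and the 6 largest decreases among called genes with a mean of at least 10 CPM in the higher group and no overlap between groups (unnamed gene models left out), the 2 members with the smallest adjusted p in each list on the question and 1 in each other list, or the most abundant member where none passed. All passing members of a list could be named where 5 or fewer passed. A gene picked by this rule is not reported here.

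On counts simulated from the means, spreads and library sizes of this comparison, with 200 of 13914 tested genes changed, the test recovered 2% of 2-fold, 44% of 4-fold, 72% of 8-fold and 86% of 16-fold changes (50 genes each) with 9 false calls. In the data 52.7% of tested genes were called, and the adjustment is stricter where few genes change. The shares recovered therefore do not give the sensitivity of the real comparison. Camera called the changed list and 0 of 3 unchanged ones, and the simulated genes had no correlation. Alternatives were DESeq2 size factors, library size only, leaving out the 20 most abundant genes, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a non-robust fit, a replicate block, an adjusted p of 0.01, glmTreat against 2-fold, and leaving out each replicate. All 6 libraries come from 1 flow cell and lane, per the labels. Figures were drawn with matplotlib 3.10.9.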

Results

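RNA was sequenced from 6 samples of mouse liver tumour of the MYC-LAP-tTA genotype, in which a tetracycline transactivator driven from a liver promoter keeps a MYC transgene on until it is switched off. In 3 samples MYC was active (MYC_On) and in 3 it had been inactivated for 4 days (MYC_Off). Each library held between 16292718 and 19265623 reads assigned to genes, so that 1 read corresponded to between 0.0519 and 0.0614 CPM (reads scaled to a fixed library total) before composition scaling. The labels do not say whether the 3 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Values below are TMM-scaled CPM as mean ± SD over 3 libraries, and log2 fold changes are MYC_Off minus MYC_On with their standard errors (SE).

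The series asks how transcription in these tumours differs with MYC active and inactivated, with the anti-tumour immune response as its stated subject. Myc itself (chromosome 15, 61985391 to 61990374, plus strand, mm10) was measured first. It stood at 778, 1020 and 852 CPM in the MYC_On libraries and at 74.7, 10.2 and 18.7 CPM in the MYC_Off libraries, in the order of their replicate numbers. The mean fell from 882 ± 122 to 34.5 ± 35.1 CPM (SD, n = 3), a log2 fold change of -4.67 (SE 0.80, adjusted p = 0.0035, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Reads of a human transgene and of the mouse gene cannot be separated on this row.

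Growth and cell division genes fell on MYC inactivation, while genes of the differentiated hepatocyte, of the acute-phase response, of antigen presentation and of several non-tumour cell types rose. Of 14130 genes tested, 7443 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4222 higher and 3221 lower in MYC_Off. Against a minimum change of 2-fold, 2621 genes were higher and 1428 lower. The direction split depended on the scaling: 56.7% of called genes were higher with TMM and 32.2% with library size only, which moved the median log2 fold change of all genes by -0.73. A few abundant liver transcripts differed between the groups, the top 20 genes taking 11.7% to 19.2% of reads in MYC_On and 29.9% to 39.1% in MYC_Off. Without MYC_On replicate 2, 2776 genes were higher.

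**Figure D1:**
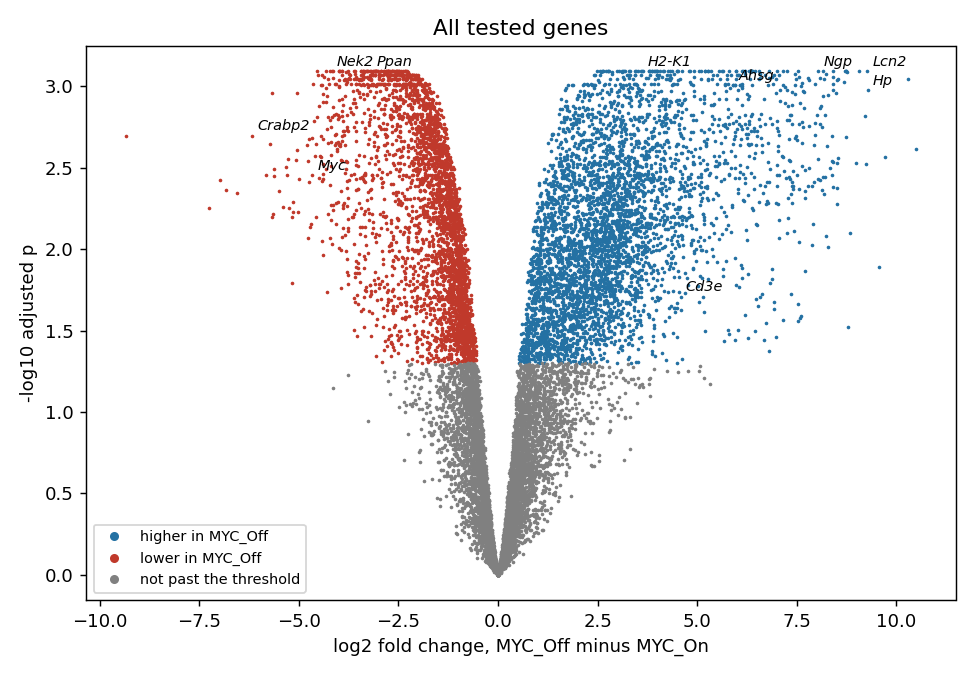
Log2 fold change (MYC_Off minus MYC_On, x axis) against -log10 adjusted p (y axis) for the 14130 genes tested, 1 point per gene, blue for genes higher and red for genes lower in MYC_Off. The 4222 higher and 3221 lower genes form the arms of the plot, with Myc at -4.67 and Lcn2 at 9.26.

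The 6 largest increases, among called genes with at least 10 CPM in the higher group and no overlap between groups, included secreted liver proteins. Hp (haptoglobin, chromosome 8, 109575128 to 109579172) rose from 12.7 ± 7.94 to 7930 ± 5270 CPM (log2 fold change 9.28, SE 1.06, adjusted p = 0.00105). Lcn2 (lipocalin 2, chromosome 2, 32384633 to 32388252) rose from 2.07 ± 1.24 to 1260 ± 394 CPM, Orm1 (an acid glycoprotein, chromosome 4, 63344560 to 63348163) from 1.41 ± 1.08 to 850 ± 919 CPM, and Vnn3 (chromosome 10, 23851462 to 23869843) from 0.769 ± 0.447 to 331 ± 198 CPM. Orm1 has close paralogs and its value is uncertain. Nr0b2, a nuclear receptor that represses bile acid synthesis (chromosome 4, 133553376 to 133556536), had 1 read over the MYC_On libraries and 1130 over the MYC_Off libraries, a scaled ratio of 1710 with a 95% counting interval of 307 to 67700. Cyp3a44 (chromosome 5, 145773983 to 145805874) had 2 and 887 reads, a ratio of 673 (186 to 5560), and also belongs to a family of near-identical genes. These intervals cover counting error only.

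By the same rule the 6 largest decreases were in Crabp2, a retinoic acid binding protein (chromosome 3, 87948666 to 87953376), from 33.4 ± 11.6 to 0.417 ± 0.589 CPM (log2 fold change -6.18, SE 0.90, adjusted p = 0.00201), and in Bmp8b (chromosome 4, 123105165 to 123132099; -5.68). Without MYC_Off replicate 1 gene Bmp8b stood at -8.77. Ccnb1ip1 (chromosome 14, 50789248 to 50807732) changed by -5.67, Rps6ka6 (chromosome X, 111388192 to 111537959) by -5.63, Nr1h5 (chromosome 3, 102939658 to 102964133) by -5.39 and Lingo3 (chromosome 10, 80832801 to 80844039) by -5.33. Exons of Bmp8b overlap those of Ppie on the other strand, and exons of Ccnb1ip1 overlap Rpph1 on the same strand, so their reads are uncertain. MYC_Off replicate 1 held the most MYC_Off reads of each of the 6 decreased genes, with 20, 1 and 1 reads of Crabp2 in replicates 1, 2 and 3. All 12 genes, increased and decreased, are annotated as protein coding.

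Genes of ribosome production and nucleotide supply fell nearly as a block. In the ribosome biogenesis list 39 of 40 tested members fell and 0 rose, with the same 39 when adjusted over the list alone, and a median log2 fold change of -2.75. Ppan, a factor of large subunit assembly, fell from 172 ± 33.2 to 18.8 ± 0.605 CPM and Grwd1 from 72.7 ± 9.33 to 11.4 ± 1.21 CPM. The list's camera adjusted p was 4.3e-29, and adjusted p = 0.15 with an estimated correlation. In the list for nucleotide and one-carbon synthesis 26 of 30 members fell (28 adjusted over the list alone; median -2.37), among them the pyrimidine enzyme Dhodh (102 ± 14.6 to 14.8 ± 1.14 CPM) and the purine enzyme Gart (153 ± 26.1 to 25.3 ± 4.14 CPM). Its camera adjusted p was 1.2e-15, and adjusted p = 0.08 with an estimated correlation. For glycolysis and nutrient uptake 15 of 22 members fell, 15 also adjusted over the list alone (median -1.38), including the amino acid transporter Slc7a5 (-3.56, SE 0.38) and Eno1 (-2.31, SE 0.27). Its camera adjusted p was 4.4e-06, and adjusted p = 0.15 with an estimated correlation. Glycolytic genes with processed pseudogenes are uncertain here.

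Cell cycle genes fell in all 3 MYC_Off libraries. All 35 mitosis genes were lower, 35 also adjusted over the list alone, with a median log2 fold change of -3.96 and library medians of -3.08, -4.57 and -4.37 relative to the MYC_On mean. The spindle kinase Nek2 fell from 82.3 ± 7.20 to 4.52 ± 1.66 CPM and Prc1, which bundles microtubules in the dividing cell, from 55.5 ± 6.01 to 5.31 ± 1.16 CPM. The mitosis list had a camera adjusted p of 4.3e-29, and adjusted p = 0.18 with an estimated correlation. Of 36 DNA replication genes 33 fell, 33 also adjusted over the list alone (median -2.75), with Uhrf1 at -4.00 (SE 0.31) and cyclin E1 (Ccne1) at -3.10 (SE 0.25). That list's camera adjusted p was 1.2e-23, and adjusted p = 0.15 with an estimated correlation. Genes of the p53 pathway, arrest and apoptosis went both ways, with 5 of 24 higher and 6 lower, the same adjusted over the list alone (median -0.22, mean 0.07, camera adjusted p = 0.6). Without MYC_On replicate 1 or 3, 3 were lower. Fas (3.34, SE 0.42) and Btg2 (1.80, SE 0.31) were among those that rose.

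Genes of the mature hepatocyte rose. All 29 tested plasma protein genes were higher, 29 also adjusted over the list alone, with a median of 3.51. Ahsg (fetuin A) rose from 451 ± 221 to 27100 ± 2150 CPM and Fetub from 18.0 ± 8.64 to 933 ± 370 CPM, and Alb took 0.112% to 0.341% of reads in MYC_On and 5.85% to 13.8% in MYC_Off. The list's camera adjusted p was 6.9e-13, and adjusted p = 0.31 with an estimated correlation. Of 35 hepatocyte metabolic enzymes 33 rose, 33 also adjusted over the list alone (median 4.62), among them Cyp8b1 and Cyp27a1 of bile acid synthesis (5.85, SE 0.56, and 3.97, SE 0.63). Here the camera adjusted p was 8e-08, and adjusted p = 0.41 with an estimated correlation, and 20 of the enzymes rose without MYC_On replicate 2 (median 4.09). Zonal hepatocyte markers rose as well, but the pericentral ones did not follow the plasma proteins in replicate 3, where the plasma protein median was 3.81. Of 12 pericentral genes 10 rose (11 adjusted over the list alone; median 5.36, camera adjusted p = 0.00098, and adjusted p = 0.41 with an estimated correlation), with Slc13a3 at 6.81. Of 15 periportal genes 11 rose, 11 also adjusted over the list alone (median 3.12, camera adjusted p = 0.0053, and adjusted p = 0.41 with an estimated correlation), with Igf1 at 4.70. The pericentral medians of the MYC_Off libraries were 4.88, 6.02 and 1.45, lowest in replicate 3, and 6 pericentral genes rose without MYC_On replicate 2 or without MYC_Off replicate 2.

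Acute-phase genes rose. Of 23 tested members 22 rose and 23 did when adjusted over the list alone, with a median log2 fold change of 6.14 and library medians of 5.14, 6.52 and 6.53. Besides Lcn2, the iron reductase Steap4 rose from 2.80 ± 1.07 to 245 ± 110 CPM. The camera adjusted p was 1.1e-14, and adjusted p = 0.17 with an estimated correlation. Fetal liver and progenitor genes divided, with 8 of 18 higher and 4 lower (9 and 5 adjusted over the list alone; median 1.82, or 1.19 without MYC_Off replicate 3, camera adjusted p = 0.15). The surface proteoglycan Gpc3 (6.16, SE 0.44) and Cd24a (6.20, SE 0.53) rose.

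**Figure D2:**
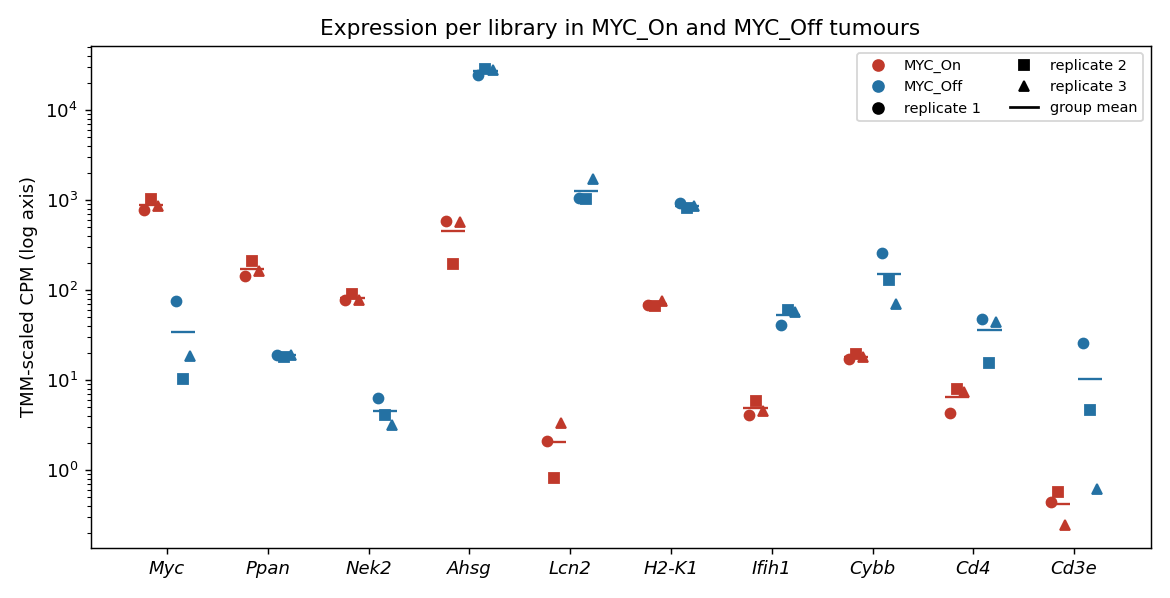
TMM-scaled CPM on a log axis for 10 named genes, 1 symbol per library with the replicate number given by its shape, red for MYC_On and blue for MYC_Off, and a bar at each group mean. Myc, Ppan and Nek2 lie lower in all MYC_Off libraries, and Cd3e spreads from 0.613 to 25.6 CPM within MYC_Off.

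With TMM scaling, the median of the macrophage genes was higher in every MYC_Off library. All 26 listed genes rose, 26 also adjusted over the list alone (median 2.70), with Cybb, a subunit of the phagocyte oxidase, from 18.2 ± 1.15 to 152 ± 96.4 CPM and the endotoxin co-receptor Cd14 from 0.641 ± 0.0416 to 41.4 ± 24.7 CPM. The camera adjusted p was 3.6e-07, and adjusted p = 0.41 with an estimated correlation. Medians of the MYC_Off libraries were 3.60, 2.03 and 1.63, and the list median was 1.71 without MYC_Off replicate 1. With library size only, 19 of the 26 genes rose (median 2.12). The number that rose was 16 without MYC_On replicate 1 and 15 without MYC_On replicate 2, with medians of 2.5 and 2.7. Both lists of macrophage activation genes rose, but in RNA of tumour tissue the cells that made these transcripts are not known. Of 20 pro-inflammatory genes 16 were higher (20 adjusted over the list alone; median 2.44, camera adjusted p = 0.00014, and adjusted p = 0.41 with an estimated correlation), including Irf1 (1.72) and Il18 (2.15), and 10 of 22 were higher without MYC_On replicate 1. Of 15 alternative activation genes 14 were higher, 14 also adjusted over the list alone (median 3.44, camera adjusted p = 1.1e-05, and adjusted p = 0.27 with an estimated correlation), including Pf4 (0.354 ± 0.0916 to 13.3 ± 3.61 CPM) and Stab1 (3.77). For Kupffer cells, the resident liver macrophages, 10 of 14 genes rose (11 adjusted over the list alone; median 2.09, camera adjusted p = 0.015, and adjusted p = 0.55 with an estimated correlation), with Nr1h3 at 1.85 and Id3 at 4.20. The Kupffer cell call was lost without MYC_Off replicate 1 (adjusted p = 0.13) and without MYC_Off replicate 2 (adjusted p = 0.053), and its library medians were 2.96, 2.30 and -0.00429. Unlike that median, Nr1h3 (102 CPM) and Id3 (10 CPM) were still raised in MYC_Off replicate 3, against MYC_On means of 38.1 and 1.96 CPM. Whether Kupffer cells gave the reads of these 2 genes was not tested. Without MYC_On replicates 1, 2 and 3 in turn, 2, 2 and 3 Kupffer cell genes rose, and without MYC_Off replicate 1, 6 of 13 did (median 1.39). The Kupffer cell medians without MYC_On replicates 1, 2 and 3 were 2.04, 2.02 and 2.08.

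Lymphocyte genes were unevenly spread over the MYC_Off libraries. Of 18 T cell genes 12 rose (15 adjusted over the list alone; median 3.86, camera adjusted p = 0.034, and adjusted p = 0.64 with an estimated correlation), and the MYC_Off library medians were 5.05, 2.24 and 0.39. Cd3e, part of the T cell receptor complex, stood at 25.6, 4.66 and 0.613 CPM in MYC_Off against a MYC_On mean of 0.421 ± 0.164 CPM. Cd4 rose from 6.54 ± 1.99 to 35.7 ± 17.6 CPM. It stood at 47.3, 15.5 and 44.4 CPM in MYC_Off, so in replicate 3 it did not follow Cd3e or the list median. Without MYC_Off replicate 1, 3 of 17 T cell genes were higher, with a median of 1.77 and a camera adjusted p of 0.24, and the call was also lost with the stricter count filter (adjusted p = 0.2). Without MYC_On replicates 1, 2 and 3 in turn, 2, 1 and 2 of 23 T cell genes were higher, and 21 of 23 were without MYC_Off replicate 3. The T cell medians without those MYC_On replicates were 3.91, 4.11 and 4.13, and camera passed each time (adjusted p = 0.024, 0.014 and 0.011). With limma-voom 2 T cell genes were higher. In the NK and cytotoxic effector list 8 of 14 genes rose, 8 also adjusted over the list alone (median 3.36, camera adjusted p = 0.058), among them Klra8 (5.95), one of a multigene family, and Ccl5 (4.45). Ccl5 lost its call without MYC_Off replicate 1 (1.86, adjusted p = 0.058). Klra8 stood at 14.5, 3.44 and 22.7 CPM in MYC_Off, highest in replicate 3, where the median of the NK list was -0.0266. For this list 1 gene was higher without MYC_Off replicate 1 (median 1.18), at most 2 of 16 without any one MYC_On replicate, and 16 of 16 without MYC_Off replicate 3. Its medians without MYC_On replicates 1, 2 and 3 were 3.29, 3.68 and 3.31. The list passed with DESeq2 size factors (adjusted p = 0.047), library size only (0.0052), no filter (0.0078), DESeq2 (0.011), limma-voom (0.042) and library size only without the 20 most abundant genes (0.017), and without MYC_On replicate 2 or 3 or MYC_Off replicate 2 or 3 (0.043, 0.037, 0.026 and 0.00065). Its adjusted p = 0.64 with an estimated correlation, and limma-voom called 2 of its 14 genes, library size only 4 of 14 and no filter 4 of 20. Of 8 tested B and plasma cell genes 3 rose, Cd22 (2.33), Cd79b (4.28) and Ighm (3.33), 3 also adjusted over the list alone, with a camera adjusted p of 0.2 for the list. With no low-count filter 6 of 19 rose and the list passed (adjusted p = 0.014), and DESeq2 called 6 of 8 higher. The B and plasma cell list had adjusted p = 0.68 with an estimated correlation. All 3 were highest in MYC_Off replicate 1, and without it the list median fell from 3.58 to 1.38. At most 1 of 11 B and plasma cell genes was higher without any one MYC_On replicate, and 10 of 11 were without MYC_Off replicate 3 (adjusted p = 0.0019). The B and plasma cell medians without MYC_On replicates 1, 2 and 3 were 4.49, 4.33 and 3.81. Without MYC_Off replicate 1 the log2 fold change was 2.48 for gene Cd3e, 1.28 for gene Cd22, 2.12 for gene Cd79b and 1.48 for gene Ighm. Of these lymphocyte genes, the gene Cd3e lost its call without any one MYC_On replicate (adjusted p = 0.0663, 0.0703 and 0.0777), as did gene Ccl5 (0.0761, 0.0816 and 0.0717) and gene Cd79b (0.0522, 0.0733 and 0.0708). The call of gene Ighm was lost without MYC_On replicate 2 (0.0824) or 3 (0.0718), and that of gene Cd22 without MYC_On replicate 1 (0.0633) or 2 (0.0623).

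Antigen presentation and interferon response genes rose in each MYC_Off library. Of 21 genes of MHC class I presentation 18 were higher, 18 also adjusted over the list alone, which added 1 lower, Psmb10 at -0.88 (median 2.80), with the peptide transporter Tap2 from 2.01 ± 0.303 to 32.4 ± 3.44 CPM and H2-K1 from 69.8 ± 4.96 to 866 ± 53.3 CPM. Class I heavy chain genes are near copies of each other, so H2-K1 is uncertain. The list's camera adjusted p was 4e-09, and adjusted p = 0.13 with an estimated correlation. Of 10 class II genes 9 rose, 9 also adjusted over the list alone (median 3.91, camera adjusted p = 0.0036, and adjusted p = 0.43 with an estimated correlation), with H2-DMa at 4.00 and Ctss at 3.55. Without MYC_Off replicate 1 the class II median was 2.59 and gene Ctss stood at 2.36. Of 30 interferon-stimulated genes 28 rose (29 adjusted over the list alone; median 2.51), among them the RNA sensor Ifih1 (4.86 ± 0.95 to 52.5 ± 10.3 CPM) and Zbp1 (2.18 ± 0.853 to 27.8 ± 6.92 CPM). That list's camera adjusted p was 2e-10, and adjusted p = 0.15 with an estimated correlation.

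Inhibitory and recruiting signals rose as well. Of 14 tested immune checkpoint genes 10 were higher, 10 also adjusted over the list alone (median 2.10, camera adjusted p = 0.011, and adjusted p = 0.41 with an estimated correlation). Cd47, a signal against phagocytosis, rose with a log2 fold change of 2.57 (SE 0.23), and Havcr2 changed by 4.05. Of the checkpoint genes 5 were higher without MYC_On replicate 1, 6 without MYC_On replicate 2 and 5 with library size only, and the median was 1.37 without MYC_Off replicate 1. The checkpoint medians without MYC_On replicates 1 and 2 were 1.85 and 2.49. Of 15 chemokine genes 12 rose, 12 also adjusted over the list alone (median 3.41, camera adjusted p = 1.2e-05, and adjusted p = 0.22 with an estimated correlation), with Csf1 at 4.53 and Ccl9 at 5.56. Of 13 dendritic cell genes 10 rose, 10 also adjusted over the list alone (median 2.74, camera adjusted p = 0.015, and adjusted p = 0.55 with an estimated correlation), with Zbtb46 at 2.74 and Itgax at 2.79. Leaving out MYC_On replicates 1, 2 and 3 in turn gave 3, 5 and 5 dendritic cell genes higher, with medians of 2.54, 2.96 and 2.86. The dendritic cell median was 1.48 without MYC_Off replicate 1.

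Markers of other cell types were measured beside these immune lists. Endothelial genes rose in 18 of 20 cases (19 adjusted over the list alone; median 2.97, camera adjusted p = 1.6e-08, and adjusted p = 0.29 with an estimated correlation), with Vwf at 5.65. Stellate cell and fibroblast genes rose in 20 of 21 cases (21 adjusted over the list alone; median 3.00, camera adjusted p = 3.4e-07, and adjusted p = 0.27 with an estimated correlation), with Postn at 2.69. Neutrophil genes rose in 13 of 14 cases, 13 also adjusted over the list alone (median 5.81, camera adjusted p = 3.1e-11, and adjusted p = 0.13 with an estimated correlation), with the granule protein gene Ngp at 8.03. All 12 erythroid genes rose, 12 also adjusted over the list alone (median 5.31, camera adjusted p = 2e-10, and adjusted p = 0.08 with an estimated correlation). Of 14 cholangiocyte genes 5 rose and 2 fell, the same adjusted over the list alone (median 1.22, camera adjusted p = 0.16), with Sox9 at 6.05. At most 1 cholangiocyte gene fell without any one MYC_On replicate, and the median was 1.91 without MYC_On replicate 2 and 0.481 without MYC_Off replicate 1. With no low-count filter 7 of 16 cholangiocyte genes rose and 1 fell, and the list stood at the threshold (camera adjusted p = 0.05 as rounded).

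**Figure D3:**
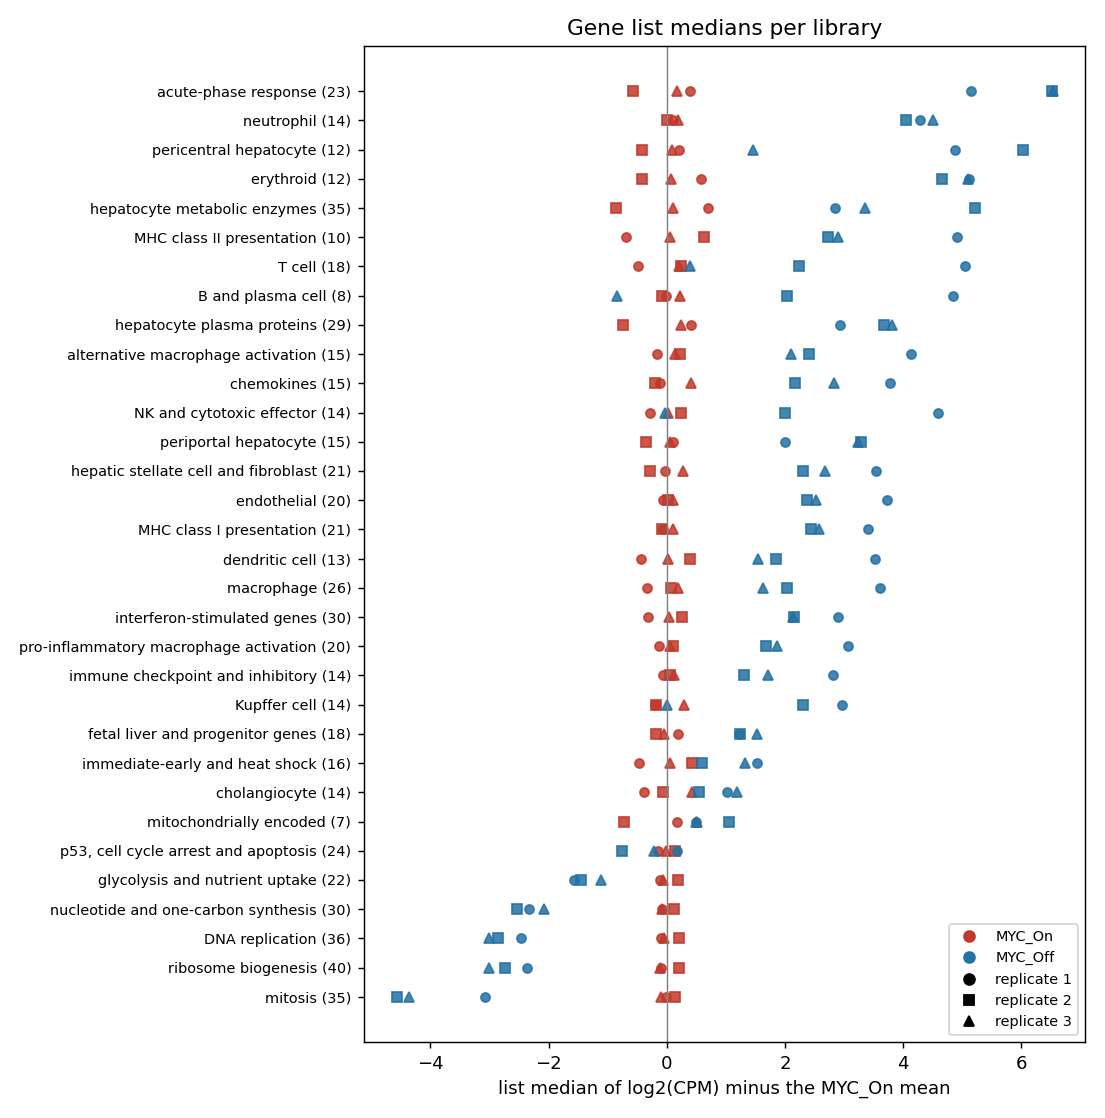
Median over each gene list of log2 CPM minus the MYC_On mean (x axis), for the 32 lists tested, with the number of tested genes in brackets, 1 symbol per library, red for MYC_On and blue for MYC_Off. The T cell medians of the MYC_Off libraries range from 0.39 to 5.05, and the mitosis medians from -4.57 to -3.08.

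Further lists were chosen to show tissue handling and library type. Of 16 immediate-early and heat shock genes 7 rose, 7 also adjusted over the list alone (median 1.27, camera adjusted p = 0.02, and adjusted p = 0.44 with an estimated correlation), with Egr1 at 3.05. This call was lost without MYC_Off replicate 1 (adjusted p = 0.11) and without MYC_On replicate 1 (adjusted p = 0.062), and 4 genes rose without any one MYC_On replicate. Of 7 mitochondrially encoded genes 0 passed in edgeR's quasi-likelihood test, adjusted over the list alone included, 1 had an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 0 (camera adjusted p = 0.37). mt-Cytb stood at 0.46 with TMM and at -0.29 with library size only. Of 3 exocrine pancreas genes tested Cela1 rose (3.20) and Clps fell (-2.78), both also adjusted over the list alone, and the gene Clps lost its call without MYC_On replicate 1 (adjusted p = 0.0669). Of 3 replication-dependent histone genes Hist1h1c (2.01) and Hist1h2bc (2.13) rose, both also adjusted over the list alone. These 2 lists were too short for camera.

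Across the 32 lists tested by camera, 21 were higher and 5 lower in MYC_Off with the preset correlation. With an estimated correlation camera called 0 lists in either direction, and 9 had an unadjusted p under 0.05. In that form camera takes its degrees of freedom from the 6 libraries, so few lists could pass at any correlation. The nucleotide synthesis and erythroid lists had estimated correlations of only 0.045 and 0.048. Both had a camera adjusted p of 0.08 there and a fry adjusted p of 0.00027. A call lost in that form therefore does not by itself show that correlation accounts for the list. Other lists had far higher estimates, such as 0.72 for mitosis, 0.82 for macrophage and 0.88 for T cell genes, against the preset 0.01. For such lists camera's preset p-values assume much less correlation than was estimated, so correlation is not excluded as a reason for them. The rotation test fry, which asks whether the genes of a list move one way without comparing them with other genes, called 20 lists higher and 5 lower. The T cell (fry adjusted p = 0.19), Kupffer cell (0.1) and dendritic cell (0.075) lists, called by camera, did not pass fry, and the fetal liver (0.01) and cholangiocyte (0.03) lists passed fry but not camera. Camera with the preset correlation also called 26 lists between groups of 3 that mixed MYC_On and MYC_Off libraries. Those groups still differed in their number of MYC_On libraries, so this is not a rate of chance calls.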

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

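The scaling of library size only without the 20 most abundant genes was chosen after seeing the data. With library size only, 2526 genes were higher and 5309 lower. Leaving out the 20 most abundant genes as well gave 3188 and 4242, against 4218 and 3211 with TMM. At an adjusted p under 0.01 the number of genes called was 4257, and 4049 in glmTreat against 2-fold, both stricter by construction. Leaving out each replicate gave 2776 to 4317 genes higher in MYC_Off, lowest without MYC_On replicate 2. The counts were 2776 to 2873 without a MYC_On replicate and 3839 to 4317 without a MYC_Off replicate. Both leave the same number of samples. The number of genes called was 5179, 5123 and 5393 without MYC_On replicates 1, 2 and 3, so this fall is not tied to 1 MYC_On sample. Across genes, MYC_On libraries correlated with each other at 0.971 to 0.98 and MYC_Off libraries at 0.86 to 0.906. Whether losing a library of the tighter group is the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower, a form of the test in which the few degrees of freedom limit what can pass. For the gene mt-Cytb the change reversed to -0.292 with library size only; the cause was not tested. For the p53, arrest and apoptosis list the median ran from -0.674 to -0.034 over the fits leaving out each replicate, and camera's direction turned without MYC_Off replicate 2; the cause was not tested. The expression of Myc stayed lower under every alternative run, with log2 fold changes from -6.08 to -4.26. Same-numbered libraries deviated from their group means with correlations of -0.26, -0.17 and 0.04, which gave no sign that the labels' numbers pair them. Deviations within groups of 3 depend on each other, so a pairing is not excluded. A replicate block called 5763 genes, 3152 higher and 2611 lower, 5687 of them shared, and the list counts stayed at 21 and 5. Under it the genes higher were 17 for macrophage, 4 for Kupffer cell, 3 for T cell, 1 for NK, 4 for dendritic cell, 5 for checkpoint, 5 for fetal and 20 for metabolic enzyme lists. Calls lost among named genes were Ccl5 and Cd22 under the block, Cd3e, Ccl5 and Ighm with limma-voom, Ccl5 and Ighm with no filter, and Cd22 with library size only. DESeq2 gave no adjusted p for 55 genes. At these depths genes below about 10 reads per library were mostly not tested.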

Other observations

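The gene lists in the first paragraphs and all tests below, apart from the splits of the samples, were chosen after the data were seen. Translation and folding genes fell together with ribosome production. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 16 were lower and 1 higher in MYC_Off (median log2 fold change -1.34, camera adjusted p = 3.8e-06, and adjusted p = 0.25 with an estimated correlation). Vars fell from 214 ± 44.7 to 34.7 ± 3.66 CPM, and Aars was the 1 that rose. All 15 genes of the chaperonin and HSP90 system were lower (median -1.77, camera adjusted p = 5.5e-08, and adjusted p = 0.18 with an estimated correlation), with Cct6a from 822 ± 22.2 to 164 ± 18.1 CPM.

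Complement genes rose, all 17 of them (median 3.93, camera adjusted p = 9.2e-10, and adjusted p = 0.25 with an estimated correlation), with C3 from 1130 ± 225 to 21800 ± 10200 CPM. Of 23 genes of cholesterol synthesis and uptake 2 rose and 1 fell (camera adjusted p = 0.75). Of 16 hepatocyte transcription factors 8 rose and 1 fell (camera adjusted p = 0.14), and of 11 genes of the MYC network 2 rose and 4 fell (camera adjusted p = 0.68).

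The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 7443 genes in edgeR's quasi-likelihood test, and the highest of the others called 0, with at most 401 at an unadjusted p under 0.05. Every other split put libraries of both kinds in each group, so the MYC difference itself widened the spread within groups. Few calls had to follow there, so the 0 is no measure of chance. For gene lists at the preset correlation the real split called 26 and the highest of the others also 26, so that 3 of the 10 splits, the real one included, called as many. The groups of the other splits still differed in their number of MYC_On libraries, so this is not a rate of chance calls either.

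Macrophage, endothelial, fibroblast, neutrophil and erythroid lists were higher in MYC_Off, and a lower share of tumour-cell RNA would raise the markers of every non-tumour cell type alike. Erythroid and neutrophil markers rose further than macrophage markers in each MYC_Off library, by 2.54 (log2, SD 0.983, n = 3) and 1.86 (SD 1.11) on average, which argues against it as the whole reason for those rises. In MYC_Off replicate 3 the T cell, NK, B cell and Kupffer cell medians were 0.393, -0.0266, -0.839 and -0.00429, against 1.63 for macrophage and 2.52 for endothelial markers. Macrophage markers differed from the mean of endothelial and fibroblast markers by -0.435 (SD 0.483), within their spread. For the macrophage rise a lower tumour-cell share therefore cannot be told apart from entry of immune cells, which was not tested.

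Hepatocyte genes rose while mitosis genes fell, and admixed liver outside the tumour, as the whole reason for both, would lower all abundant fetal transcripts about as far as the mitosis list (-3.96), but the 9 fetal list members at 50 CPM or more in MYC_On had a median of 0.427 (SD 2.55), with Igf2bp1 (-4.39), Hmga1 (-3.88) and Peg10 (-3.76) near the mitosis value. The median of all 9 per MYC_Off library was -0.579, -0.148 and -0.0526, against -3.08, -4.57 and -4.37 for mitosis, and Afp was higher in each while H19 and Igf2 exceeded all MYC_On libraries in replicate 3 only. From MYC_Off replicate 2 to 3 pericentral genes changed by -4.56 relative to plasma proteins (median absolute deviation 2.57 over 12 genes). Whole lobules with the same zonal expression in both libraries would not give this. The comparison rests on 1 library and a spread over genes. Admixed liver with low pericentral expression is therefore not excluded in replicate 3. From replicate 1 to 2 the same difference was 0.469 (deviation 1.40), so admixed lobules may contribute there. Differentiation of the tumour cells on loss of MYC stays open as the biological alternative.

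MYC_Off replicate 1 kept 8.47% of the MYC_On level of Myc, against 1.15% and 2.12% in replicates 2 and 3. Its medians were the highest of the MYC_Off libraries for the T, B, NK, Kupffer, dendritic and macrophage lists. The same held for the class II, endothelial and fibroblast lists, while the neutrophil median was highest in replicate 3 (4.51). Tumour cells that still express the transgene may be the source of the Myc reads. The 6 genes at 1% or less of their MYC_On level in each of the other MYC_Off libraries, and at 20 CPM or more in MYC_On, kept a median of 5.79% in replicate 1. The same choice made for replicates 2 and 3 gave 0 genes, so at this limit there is no control. Over the 6 limits looked at, the median ran from 5.79% to 9.86%, and at the loosest, a mean of 5%, 97 genes kept 9.86% in replicate 1 while 18 and 26 genes chosen for replicates 2 and 3 kept 0.846% and 2.31%. Genes chosen for replicates 2 and 3 needed a low mean that included replicate 1, so their small shares follow in part from the choice. Leftover MYC-expressing cells and a weaker response throughout replicate 1 would both leave such shares in replicate 1, so the explanations cannot be told apart. Ptprc, a gene of leukocytes in general, stood at 228, 60.5 and 28.9 CPM in MYC_Off replicates 1, 2 and 3. Reads of the transgene and of the mouse gene cannot be separated, so which cells gave the Myc reads is not known.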
